A study of Homo sapiens with 4 samples.

How the data were processed

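The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) for LMTK3, lemur tyrosine kinase 3, in a pair of human breast cancer cell lines. MCF7 is an oestrogen receptor-positive line of luminal type, and MDA-MB-231 is an oestrogen receptor-negative line of mesenchymal type. Per the labels' protocols, sonicated nuclei were cleared, LMTK3-bound DNA was isolated with a monoclonal antibody (clone 2H6), and libraries followed standard Illumina preparation. The labels describe 4 samples, which are 1 ChIP and 1 input library per cell line, so each group holds 1 sample. Peak lists of the 2 ChIP libraries were analysed. The input libraries were not analysed here on their own.

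The reads were aligned with Bowtie to the human build hg19, per the submitters' processing notes. The aligner version is not given in the sources used here. Peaks carry names in the style of MACS, a peak caller, per the file contents. Its version, its settings and whether the input library served as control are not given in the sources used here. The deposited score is 1 number per peak and is the authors' own. Its lowest value is 50 in both lists. In files of this layout from early MACS versions the score is a p-value on a negative log10 scale multiplied by 10, which neither the labels nor the files state. Scores grow with sequencing depth, so they were ranked within a list and not compared in size between lists as a measure of binding. Where the same score cut or class is given for both lists, it need not be equally strict in both. Peaks were deposited separately for each ChIP library, and no peak overlaps another in its own list. The number of reads per library is unknown, so no limit of detection can be given, and a position without a peak means only that none passed the authors' threshold.

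Positions are hg19 and are printed counting from 1. No hg19 sequence or gene annotation was used here, so peaks are identified by position and not by gene. Planned comparisons with genes, promoters, gene lists, assembly gaps and repeats were not run for the same reason. The planned rule named the 10 highest-scoring peaks of each list and the 10 overlapping pairs with the lowest sum of score ranks, each rank taken as a share of its list. Its parts on genes could not be applied. The other positions named in the text were chosen after their values were seen.

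All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was called shared when at least 1 bp overlapped a peak of the other list. Observed values were set beside 1000 random placements of the same peaks with a fixed seed. Each peak kept its width and chromosome and was placed between the first and last peak position of that chromosome in either list. A second set of placements moved each peak by at most 100 kb. Values by score class used 200 placements. Peaks with a neighbour in the same list within 10 kb were counted as clustered. Chromosome lengths were taken as the last peak position in either list. Chromosome ends were taken as the first and last peak positions, and only the long-arm end was used for chromosomes 13, 14, 15, 21 and 22. The comparison by distance to chromosome ends and the score classes were chosen after the data were examined. The main settings of the planned comparisons and most alternatives were set before the data were examined. Rank cuts other than the top 10 were not in the plan. Nor were the 1 Mb bins, the 5 Mb windows and the densities on either side of a peak-free stretch.

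Shares carry 95% Wilson intervals, and ratios of shares carry 95% log-normal intervals. These cover counting error over peaks only. Without replicate ChIP libraries no test between the cell lines was possible, and no p-values are given. Every difference is one between 2 lists. The overlap procedure was tested on simulated data for the MCF7 list against the MDA-MB-231 list. With 3086 simulated peaks and 400 planted overlaps, 406.4 were recovered after subtraction of the random level. Planted peaks began at the start of a peak of the other list, so they overlapped by construction. The simulation therefore checks only the counting and the subtraction. Alternatives were stricter score thresholds, the longer list reduced to the length of the shorter, other definitions of overlap, other distances, local placement, and removal of chromosomes 17 and 20.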

Results

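LMTK3, lemur tyrosine kinase 3, is a kinase linked to oestrogen receptor signalling in breast cancer. Its chromatin binding was profiled by ChIP-seq in MCF7 and MDA-MB-231 cells, with 1 ChIP library per cell line and no replicate. The design addressed where LMTK3 sits on chromatin in each cell type. The deposited result is a peak list per ChIP library, made by the authors, with a position and a score for each peak. Read depth is unknown for both libraries. Differences between the lists therefore have no replicate check, and intervals cover counting error over peaks only.

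The MDA-MB-231 list was far longer than the MCF7 list. It held 24516 peaks covering 24.1 Mb, against 3086 peaks covering 3.92 Mb in MCF7, a ratio of 7.94 in number. Over all peaks MDA-MB-231 widths were lower, with a median of 771 bp (quartiles 597 and 1108) against 1035 bp (quartiles 858 and 1389). At high scores the order depended on how many peaks were taken. The medians in MDA-MB-231 and MCF7 were 1150.5 and 1192.5 bp in the top 50 of each list, 1797.5 and 1261.5 bp in the top 300, and 1242.5 and 1250 bp in the top 10% of each list. Most peaks in both lists lay close to the lowest reported score of 50. The median score was 60.8 in MCF7 and 64.5 in MDA-MB-231, and scores of 100 or more were reached by 196 peaks (6.35%) and 2798 peaks (11.4%). A small set stood far above the rest. Scores of at least 500 were reached by 15 peaks in MCF7, up to 1348, and by 28 peaks in MDA-MB-231, up to 2431.

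The strongest MCF7 sites were also MDA-MB-231 peaks, while 2 of the 10 strongest MDA-MB-231 sites had no MCF7 peak. The highest-scoring MCF7 peak, on chromosome 19 at 36119361 to 36120548 (score 1348), overlapped the second-ranked MDA-MB-231 peak (36119389 to 36120779, score 2097). The top MDA-MB-231 peak, on chromosome 4 at 120375276 to 120376459 (score 2431), overlapped the MCF7 peak ranked 2 (120375272 to 120376486, score 1347), and the midpoints of this pair were 11.5 bp apart. On chromosome 17, the MCF7 peak at 36981041 to 36982181 (score 1090) ranked 4 in its list, as did its MDA-MB-231 partner at 36981059 to 36981986 (score 1750). The site on chromosome 3 at 52443391 to 52444587 in MCF7 ranked 5 there (score 1024) and 3 in MDA-MB-231 (score 1940). On chromosome 2, the peak at 29092612 to 29093718 ranked 3 in MCF7 (score 1123) and 15 in MDA-MB-231 (score 773).

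Further strong pairs lay on chromosomes 10, 9, 4 and 17. The MCF7 peak on chromosome 10 at 113942951 to 113944104 ranked 6 and its partner 7 (scores 793 and 1166). On chromosome 9, 94877068 to 94878305 ranked 7 in MCF7 and its partner 18 in MDA-MB-231 (scores 791 and 682). Chromosome 4 carried 2 more such sites. The MCF7 peak at 8441920 to 8443119 ranked 8 and its partner 9 (scores 754 and 1099), and that at 119512451 to 119513308 ranked 10 and its partner 11 (scores 730 and 1047). The MCF7 peak on chromosome 17 at 685057 to 686038 ranked 9 and its partner 8 (scores 752 and 1139). These 10 pairs were compact, with MCF7 widths between 858 and 1238 bp, and their midpoints lay a median of 62.8 bp apart. They are also the 10 highest-scoring MCF7 peaks. This match is partly built in, since a rank in the shorter MCF7 list weighs more in the sum.

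**Figure D1:**
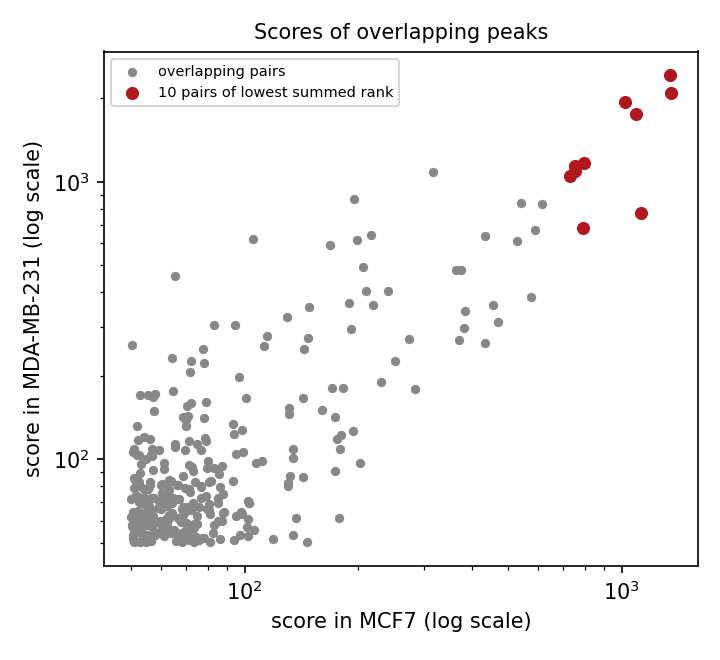
Each point is a pair of overlapping peaks, with its MCF7 score on the x axis and its MDA-MB-231 score on the y axis, both on log scales and without unit. The 10 pairs with the lowest summed rank (red) have MCF7 scores from 730 to 1348 and MDA-MB-231 scores from 682 to 2431.

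Over the whole lists most peaks overlapped no peak of the other list. Only 311 of the 3086 MCF7 peaks (10.1%, interval 9.06 to 11.2) overlapped an MDA-MB-231 peak, and 316 of the 24516 MDA-MB-231 peaks (1.29%, interval 1.16 to 1.44) overlapped an MCF7 peak. The MDA-MB-231 share is bounded by list length, as 3086 MCF7 peaks can meet only a small part of 24516. Random placement on the same chromosomes gave a mean of 2.02% for MCF7 and at most 2.82%, so the observed share was 4.98 times the random mean. When peaks were moved by at most 100 kb, the random mean was 2.97% and the highest value 4.02%. For MDA-MB-231 the whole-chromosome placements gave a mean of 0.261% and at most 0.371%. Across the 311 shared MCF7 peaks and their best partners, Spearman's rho of the scores was 0.50. This value is across peaks, which are not independent replicates.

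Sharing rose with the score. Read depth is unknown, so an equal score need not be equally strict in both lists. All of the top 25 MCF7 peaks overlapped an MDA-MB-231 peak (interval 86.7 to 100%), as did 43 of the top 50 (86.0%) and 65 of the top 100 (65.0%). From the MDA-MB-231 side, 8 of the top 10, 21 of the top 25 (84.0%), 33 of the top 50 (66.0%) and 48 of the top 100 (48.0%) overlapped an MCF7 peak. In MCF7, 35 of the 38 peaks with a score of 200 or more were shared (92.1%, interval 79.2 to 97.3), against 95 of the 1484 peaks with scores from 50 to 60 (6.40%, interval 5.27 to 7.76). Even in this lowest class the share was above the highest of 200 placements within 100 kb (4.18%). In MDA-MB-231, 53 of the 186 peaks with a score of 200 or more were shared (28.5%, interval 22.5 to 35.4), against 84 of the 9366 peaks with scores from 50 to 60 (0.897%).

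**Figure D2:**
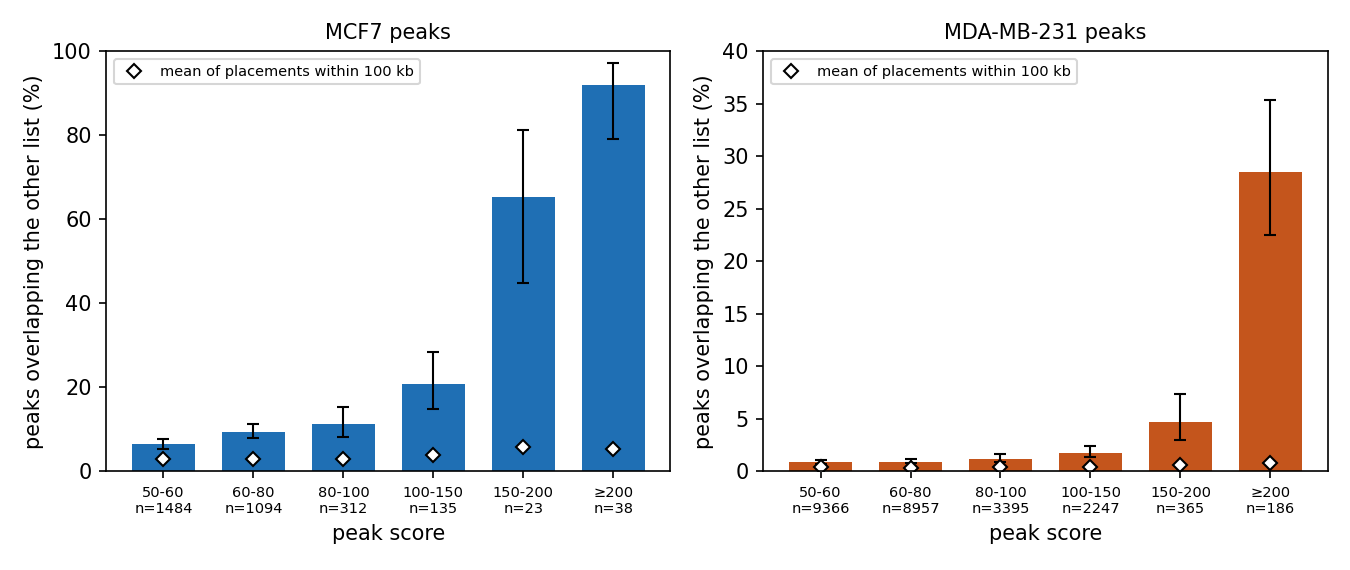
Bars give the percent of peaks that overlap the other list, by peak score class (x axis, no unit), for MCF7 (left) and MDA-MB-231 (right, shorter y axis), with 95% Wilson intervals and the number of peaks. Diamonds mark the mean of placements within 100 kb. The share rises from 6.40% to 92.1% in MCF7 and from 0.897% to 28.5% in MDA-MB-231.

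Some strong MDA-MB-231 sites had no MCF7 counterpart, and they were of different shapes. The peak ranked 5, on chromosome 1 at 243264755 to 243265766 (score 1586), was 1012 bp wide, and the nearest MCF7 peak was 235 kb away. A compact peak on chromosome 12 at 112279386 to 112280842 (score 758, rank 16) had its nearest MCF7 peak at 378 kb. In contrast, the peak ranked 6, on chromosome 16 at 33237020 to 33241700 (score 1390), spanned 4681 bp with an MCF7 peak 5.42 kb away. The peak ranked 17, on chromosome 2 at 87718882 to 87731292 (score 740), spanned 12411 bp. Among MDA-MB-231 peaks with a score of 200 or more, the 53 shared peaks had a median width of 1015 bp (quartiles 898 and 1220), and the 133 others 2188 bp (quartiles 1534 and 3664). The gap narrowed as the score fell. At scores from 150 to 200 the medians were 1115 bp (quartiles 1007 and 1326) for 17 shared and 1673.5 bp (quartiles 1163 and 2359) for 348 unshared peaks, and from 100 to 150 they were 1080 bp for 40 shared and 1144 bp for 2207 unshared peaks. Over all peaks the shared ones had the larger median, 903 against 769 bp in MDA-MB-231 and 1288 against 1017 bp in MCF7. The tenth-ranked MDA-MB-231 peak, on chromosome 3 at 16305964 to 16307085 (score 1088), was shared but ranked 25 in MCF7 (score 316).

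Strong MCF7 sites without an MDA-MB-231 peak began lower in the ranking. The highest, on chromosome 19 at 15559646 to 15561479, ranked 26 (score 300.1) and lay 10.5 kb from the nearest MDA-MB-231 peak. It was followed by chromosome 17 at 4606914 to 4607972 (rank 29, score 264). A peak on chromosome 3 at 110960490 to 110962684 (rank 44, score 191) was 1089 kb from any MDA-MB-231 peak.

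MDA-MB-231 peaks were concentrated near chromosome ends, which in the human genome are often gene-dense. Within 5 Mb of an end lay 5537 peaks (22.6%, interval 22.1 to 23.1), against a random mean of 7.89% and a highest random value of 8.52%. In MCF7 the share was 333 peaks (10.8%, interval 9.74 to 11.9), against a random mean of 7.23% and a highest value of 8.72%. The excess was therefore 2.86 times random in MDA-MB-231 and 1.49 times in MCF7. In the top 10% of scores the MDA-MB-231 share was 32.0%, 3.88 times random. The MCF7 share there was 11.3%, 1.53 times random, but with few peaks the placements ranged up to 11.97%. The densest 1 Mb bin in MDA-MB-231 was 1 to 2 Mb on chromosome 19, with 71 peaks against 1 in MCF7. Next came 134 to 135 Mb on chromosome 10, with 70 peaks against 0, and 1 to 2 Mb on chromosome 5, with 69 against 4. Chromosome 20 from 61 to 62 Mb also held 69, against 0. These bins were picked for their MDA-MB-231 numbers, and that list is 7.94 times longer. Lower MCF7 numbers in them are therefore partly built in. Among MDA-MB-231 peaks with a score of 200 or more, 66 of the 133 unshared peaks lay near an end (49.6%, interval 41.3 to 58.0), against 8 of the 53 shared peaks (15.1%, interval 7.85 to 27.1). Over all MDA-MB-231 peaks the gap was smaller, with 22.7% of unshared (interval 22.1 to 23.2) and 17.4% of shared peaks (interval 13.6 to 21.97) near an end. In MCF7 the direction was the opposite, with 10.02% of unshared (interval 8.96 to 11.2) and 17.7% of shared peaks (interval 13.8 to 22.3). Shared peaks are the same sites seen from either list, with 55 near an end in each. The opposite directions therefore reflect the different shares near ends of the whole lists, 22.6% in MDA-MB-231 and 10.8% in MCF7.

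**Figure D3:**
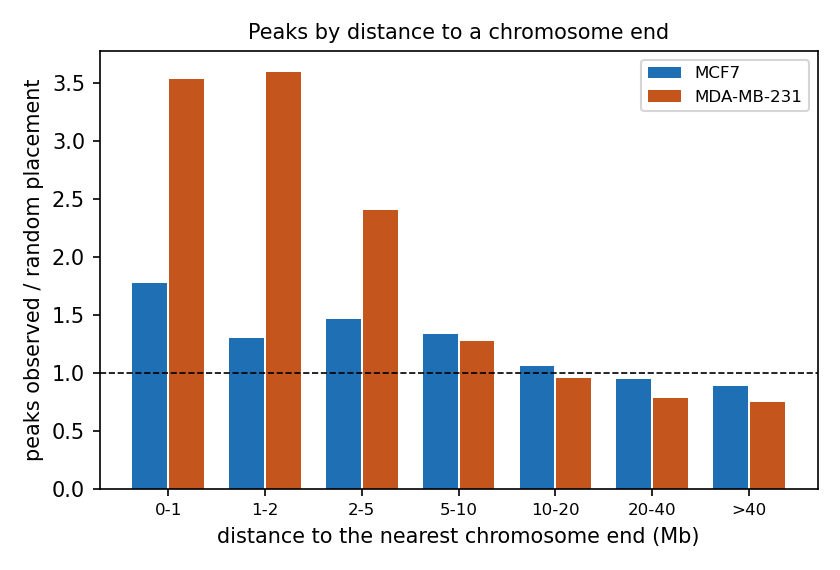
Bars give the number of peaks observed divided by the mean of 100 random placements (y axis, ratio), by distance to the nearest chromosome end in Mb (x axis). MDA-MB-231 reaches 3.54 in the first Mb and 0.75 beyond 40 Mb, and MCF7 reaches 1.78 and 0.88. The dashed line marks 1.

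The lists also differed in how peaks were shared out among chromosomes. Of the 23 chromosomes compared, 7 held a larger share of the MDA-MB-231 list and 7 a larger share of the MCF7 list with an interval that excluded 1. Chromosome Y was not among those compared. It held 4 MCF7 and 15 MDA-MB-231 peaks, which were included in the overlap counts. Chromosomes 18 and 11 had the highest ratios of MDA-MB-231 to MCF7 shares. Chromosome 18 held 499 of its peaks (2.04%) against 27 in MCF7 (0.875%), a ratio of shares of 2.33 (interval 1.58 to 3.42). Chromosome 11 followed, with 1396 peaks (5.69%) against 78 (2.53%) and a ratio of 2.25 (interval 1.80 to 2.82). With the MDA-MB-231 list reduced to its top 3086 peaks the ratios were 1.67 on chromosome 18 and 2.09 on chromosome 11. Chromosome 3 differed most in the other direction, with 266 MCF7 peaks (8.62%) against 1166 (4.76%) and a ratio of 0.55 (interval 0.49 to 0.63). On chromosome 12 the ratio was 0.68 (interval 0.59 to 0.80). Chromosome 19 had the highest peak density in both lists, with 1.98 peaks per Mb in MCF7 and 21.7 in MDA-MB-231. The copy number of these chromosomes in the cell lines was not measured here.

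**Figure D4:**
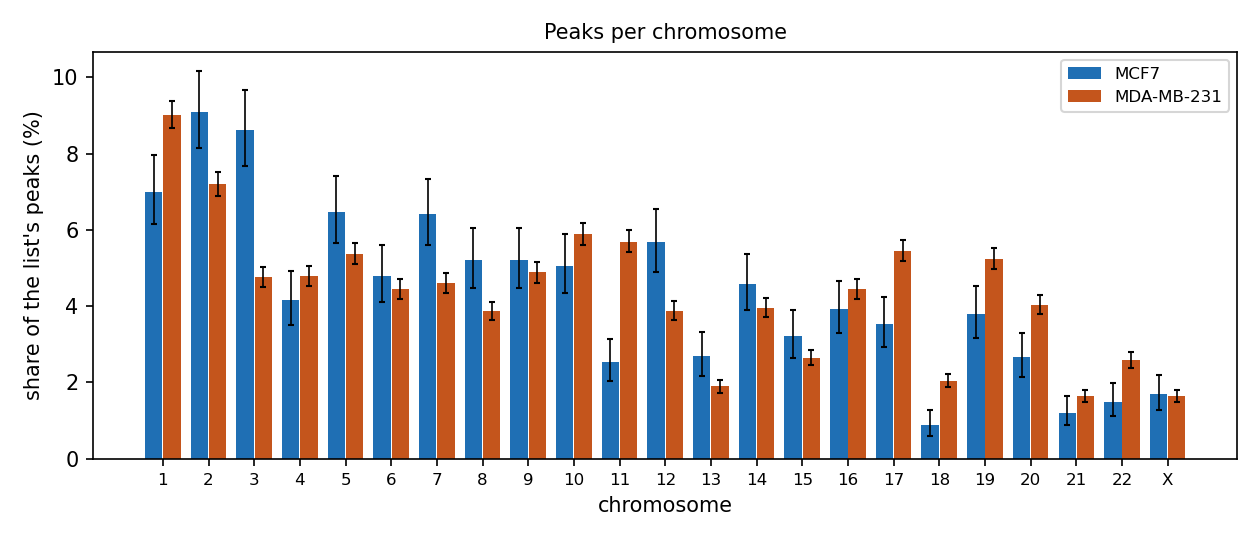
Bars give the percent of each list's peaks (y axis) on each chromosome (x axis), with 95% Wilson intervals. Chromosome 3 holds 8.62% of MCF7 and 4.76% of MDA-MB-231 peaks, and chromosome 18 holds 0.875% and 2.04%.

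Peaks lay in close groups more often than random placement gave. Placement was even along each chromosome, so uneven density, such as that near chromosome ends, can also give close groups. The contribution of such density was not separated here. In MDA-MB-231, 8267 peaks (33.7%, interval 33.1 to 34.3) had a neighbour within 10 kb, against a random mean of 19.1% and a highest value of 20.1%. In MCF7, 167 peaks did (5.41%, interval 4.67 to 6.27), against a mean of 2.54% and a highest value of 3.82%. In the upper 50% of MCF7 scores, 2.20% had a neighbour, 1.73 times the random mean, and with fewer peaks the placements ranged up to 2.85%. The groups with most peaks in MDA-MB-231 lay on chromosome 4 at 1188287 to 1238916 and on chromosome 20 at 60993643 to 61052030, each with 9 peaks. No MCF7 group held more than 3 peaks, and these included chromosome 6 at 13419409 to 13427200 and chromosome 8 at 105117761 to 105131656.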

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

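None of the 15 results changed direction under the alternatives run. Peak numbers and widths of a single list have no direction, so they could not reverse. Of 72 values, 31 stayed within their counting interval or, for widths, within their quartiles, and 41 moved outside. Score thresholds set the list lengths by construction, with 1543 and 12258 peaks in the upper 50% of MCF7 and MDA-MB-231 scores and 309 and 2452 in the top 10%. With both lists at their upper 50%, 9.98% of MCF7 peaks were shared, against 10.1% over all peaks. This was 8.69 times random, against 4.98, because the random mean fell from 2.02% to 1.15%. With both at the top 10%, 21.4% of MCF7 and 2.69% of MDA-MB-231 peaks were shared. The MCF7 overlap was then 68.7 times a random mean of only 0.311%. The median width in the top 10% was 1242.5 bp in MDA-MB-231 and 1250 bp in MCF7. With the MDA-MB-231 list reduced to its top 3086 peaks, 3.66% of either list was shared. For MCF7 this was 11.04 times a random mean of 0.332%. An overlap of at least 50% of both peaks gave 6.97% and 0.877% and 13.1 times random, and midpoints within 1 kb gave 5.66 times. Allowing up to 10 kb between peaks gave 26.9% and 4.13% and 1.68 times, and placement within 100 kb gave 3.40 times. Shares with a neighbour were 2.20% and 22.7% in the upper 50% of scores and 0.647% and 8.69% in the top 10%, with 10.6% in the reduced MDA-MB-231 list. In MDA-MB-231 the random shares fell faster than the observed ones. Its ratio to random therefore rose from 1.77 over all peaks to 2.17, 3.49 and 3.46 in these settings. The MCF7 values, 1.73 and 2.38 times random against 2.13 over all peaks, no longer exceeded the highest placements (2.85% and 1.94%), which spread more around their mean with fewer peaks. Within 1 kb the shares were 0.972% and 6.82%, where MCF7 was also inside the random range (up to 1.23%), and within 100 kb they were 31.5% and 85.2%. At 100 kb the MDA-MB-231 share was only 1.04 times its random mean of 81.8% (highest 82.7%), against the 1.77 times at 10 kb, and the MCF7 share was 1.54 times random. The MDA-MB-231 share near ends was 24.98% in the upper 50%, 32.0% in the top 10%, 30.9% in the reduced list and 17.6% with groups counted once. Within 2 Mb of an end it was 11.2% against 4.37% in MCF7, and within 10 Mb 32.6% against 20.3%. The MCF7 share near ends in the top 10%, 11.3%, was 1.53 times random against 1.49 over all peaks, but inside the wider random range of fewer peaks (up to 11.97%). The ratio of shares on chromosome 3 was 0.47 in the upper 50% and 0.37 in the top 10%. In the top 10% it was 0.58 on chromosome 12 and 4.91 on chromosome 18, the latter resting on 1 MCF7 peak, while the reduced MDA-MB-231 list gave 1.67 on chromosome 18 and 2.09 on chromosome 11. Leaving out chromosomes 17 and 20, leaving out peaks near ends, or placing peaks outside the longest peak-free stretches (the latter settings chosen after the data were examined, as were the alternatives for chromosome ends), left the overlap within its interval. Causes were not tested beyond the construction of each setting. Alternatives that need genes, gaps or repeats were not run. Unknown read depth limits every statement on sites without a peak.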

Other observations

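The MCF7 peaks on chromosome 18 were unevenly placed. Before the long peak-free stretch that ends at 18887444, MCF7 had 16 peaks, or 1.04 per Mb, and MDA-MB-231 had 167, or 10.9 per Mb. After it, MCF7 had 11 peaks in 59.1 Mb, or 0.186 per Mb, and MDA-MB-231 had 332, or 5.62 per Mb. On chromosome 11 MCF7 density was low on both sides of the corresponding stretch, at 0.439 and 0.702 per Mb, with 9.89 and 11.3 in MDA-MB-231. On chromosome 3 the MCF7 density was 1.06 per Mb before the stretch and 1.64 after it, with 7.02 and 5.16 in MDA-MB-231. On chromosome 12 the MCF7 density was 0.75 and 1.56, with 5.19 and 8.08 in MDA-MB-231.

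Regions in which MCF7 peaks were dense relative to MDA-MB-231 included chromosome 8 from 105 to 110 Mb, with 22 peaks against 23, and chromosome 15 from 95 to 100 Mb, with 20 against 21. The densest 5 Mb window of MCF7 held 22 peaks, and 1000 random placements reached up to 23, so this density alone is within the random range. Across 603 windows of 5 Mb, the peak numbers of both lists had a Pearson's r of 0.38 and a Spearman's rho of 0.44. Without windows near chromosome ends these were 0.40 and 0.44. Windows are not independent replicates.

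For the patterns below, the tests of MCF7 as a shorter version of the other list, of peak width and of copy number were chosen after the result was seen, and those on chromosome ends after the data were examined but before their own values were seen.

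Few MCF7 peaks overlapped the list that is 7.94 times longer. The overlaps found among the lower-scoring MCF7 peaks were 2.20 times those of placements within 100 kb (interval 1.81 to 2.66), which argues against random positions in the same neighbourhoods. Lower depth or enrichment of the MCF7 library stays open. In the upper 50% of MCF7 scores 13.9% of peaks recurred (interval 12.2 to 15.7), but with 311 overlaps in the whole list this share could not exceed 20.2%, so the test cannot decide. Many weak peaks that do not recur may be calls close to the threshold, or sites particular to a cell line, and without replicate libraries these stay open.

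The highest-scoring MCF7 peaks lay at positions of MDA-MB-231 peaks. Wide artefact regions were argued against. The 43 shared peaks among the top 50 of MCF7 had a median width 1.13 times that of the list (interval 1.08 to 1.196). Width cannot tell compact artefact sites from binding sites, and input coverage was not used here, so such artefacts stay open. Copy number gain was left undecided: the fullest chromosome held 11.6% of these peaks (interval 5.07 to 24.5), and 27.9% lay within 5 Mb of another of them (interval 16.7 to 42.7), against a random mean of 17.6% and a highest random value of 48.8%. A candidate explanation for these MCF7 peaks is a common set of compact sites recognised by the antibody in both lines. Binding of LMTK3 itself and of another protein recognised by the same antibody could both give this, and no sample without LMTK3 was analysed here.

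MDA-MB-231 peaks gathered near chromosome ends. Peaks just above the threshold are argued against as the cause, since in the top 10% of scores the share near ends was 3.88 times random (interval 3.66 to 4.11). Counting peaks within 10 kb once left 2.28 times random (interval 2.21 to 2.35), which argues against a few dense runs as the whole cause. The length of the list is argued against too. Reduced to its top 3086 peaks, the MDA-MB-231 list had a share 2.87 times that of MCF7 (interval 2.56 to 3.22). These peaks include the top 10% of scores, so this is not separate evidence from the first value. Base composition bias of the library, copy number and a difference between the cell lines stay open and were not tested, as neither sequence nor input coverage was used here.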
